A study of Mus musculus with 8 samples.

How the data were processed

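RNA of sorted mouse colon fibroblasts was measured on 8 Affymetrix mouse transcriptome arrays, 4 for the CD90-negative and 4 for the CD90-positive population, one colour and one array per sample. Per the labels' protocols, the RNA was extracted with a bead-based cell kit including DNA digestion, its integrity was measured on a BioAnalyzer, and 2 ng was amplified and labelled with an in vitro transcription pico kit. The series' design text says that both populations came from 4 mice, and the labels do not tie samples to mice. Amplification from so little RNA can add spread to dim transcripts.

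The authors deposited log2 values, one per transcript cluster and array. Per the submitters' processing notes, Affymetrix Expression Console 1.1 and RMA were used, which corrects the background, quantile-normalizes the arrays and summarises the probes of a cluster on the log2 scale. Which settings were used is not given in the sources used here. The deposited log2 table held 72688 rows, of which 6732 were control rows and 65956 transcript clusters. In 563 clusters the mean was above 16, the largest log2 value that a 16-bit scan allows, so the deposited scale is stretched or shifted against raw brightness and the size of a fold cannot be read as a ratio of RNA amounts.

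The platform's probe annotation named 1 gene for 31258 clusters, several for 1492 and none for 33206; these last are unnamed here, not without a gene. Symbols were updated through the gene identifiers of RefSeq's mouse annotation (assembly GRCm38.p6). Clusters naming 1 gene covered 30702 genes, and of the 731 symbols in the gene lists 672 were measured. The array's genome build is not given in the sources used here, so no coordinates are printed. Among the tested genes 226 had values identical to another gene's, 22 of them called.

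Clusters had to reach 5.36, the median (50th percentile) of all cluster values, in at least 4 of the 8 samples, whatever their population. A gene was represented by its cluster with the highest mean over the 8 samples. The 17221 genes left were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05, without a block. Gene lists, 29 of pathways and 16 of cell types, and 2 lists used only as checks (surface markers of the sort and sex-linked genes) were fixed before the data were examined. The semaphorin list was chosen with background knowledge of a link between semaphorins and CD90-positive colon fibroblasts. The 42 lists with at least 4 tested genes were tested with limma's camera at its preset correlation of 0.01, which compares a list with all other genes, and again with the correlation estimated from the data, with Benjamini-Hochberg adjustment over the lists. Member counts were taken over all genes and adjusted over the list alone. Thy1 and the means of 13 cell type lists were compared by two-sided exact permutation tests over the 70 assignments of the 8 samples. These take the samples as exchangeable, although both populations came from the same 4 mice; if the samples were paired, swaps within pairs would allow 16 assignments and no exact p under 0.125.

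The genes named were also fixed by a rule before the data were examined. It took the 5 genes of the sort gate, and the 12 genes with the highest and the 12 with the lowest difference among called genes whose populations did not overlap. Predicted genes, RIKEN clones, small RNAs and ribosomal pseudogenes were to be skipped there, and 0 were. It also took up to 4 genes with the smallest p per pathway list, and per cell type list the 3 with the highest mean and up to 3 with the smallest p. Genes outside the rule are marked as added.

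The tests were checked on simulated data for this comparison, with 17221 genes drawn independently from the measured means and spreads, without differences between mice. Of these, 200 were changed singly, and a list of 20 more was shifted by 1 (log2). Of the genes changed by 0.5, 1 and 2 (log2), the limma step called 53.4%, 90.5% and 98.4% in the right direction. Of the 191 genes called, 14 were unchanged ones. The simulation changed a far smaller share of genes than was called in the data. Alternatives changed the filter, the normalization, the variance model, the array weights, the choice of cluster, the block, the list test and the samples left out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and tables prepared with pandas 2.3.3.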

Results

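Gene expression was measured in fibroblasts of the colon of C57BL/6J mice that had been sorted by flow cytometry into cells without and cells with CD90 on their surface. CD90, coded by Thy1, is a surface glycoprotein found on thymocytes, neurons and part of the fibroblasts of many tissues. Before this split the cells had been gated as lacking Epcam (an epithelial surface protein), CD45 (coded by Ptprc and carried by leukocytes) and CD31 (coded by Pecam1 and carried by endothelium) and as carrying gp38, the podoplanin coded by Pdpn. Each population had 4 samples, one array each, and samples keep the numbers of their titles: 13, 15, 17 and 19 for the CD90-negative population and 14, 16, 18 and 20 for the CD90-positive one. The samples came from 4 mice, and the labels do not say which samples share a mouse, so p-values measure the spread between these samples. The comparison asks how the CD90-positive fibroblasts differ from the CD90-negative ones in gene expression. Values below are log2 expression as deposited, given as mean ± SD (n = 4 in each population), and differences are CD90-positive minus CD90-negative. The number of arrays limits the precision. The median of all transcript clusters lay between 5.3 and 5.41 on the 8 arrays. The deposited scale reached 19.85, above the 16 that a 16-bit scan allows, so a fold is a fold on this scale. A gene marked "(added)" fell outside the fixed naming rule and was chosen after its values were seen.

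Thy1 was higher in every CD90-positive sample than in every CD90-negative sample. Its mean was 7.69 ± 0.47 against 5.52 ± 0.046, a difference of 2.17 from a CD90-negative mean near the filter on dim clusters at 5.36 (two-sided exact permutation test, p = 0.0286, the smallest that 4 samples against 4 can give; limma adjusted p = 8.11e-05). Exact tests took the 8 samples as exchangeable, since no label pairs them; swaps within 4 pairs could give no p under 0.125. Within the CD90-positive population Thy1 ran from 7.03 in sample 14 to 8.11 in sample 16. Pdpn was bright in both populations, at 13.17 ± 0.2 and 13.2 ± 0.22 (exact p = 0.8). Epcam was at 8.06 ± 0.83 and 8.19 ± 0.83 (exact p = 0.743), and Pecam1 at 6.24 ± 0.34 and 6.59 ± 0.51 (exact p = 0.257). Pecam1 was called higher without sample 14 (difference 0.59, limma adjusted p = 0.0429), without samples 13 and 14, a setting chosen after seeing the data (0.73, limma adjusted p = 0.0062), and with array weights (0.67, limma adjusted p = 0.0207). Ptprc lay under the filter on dim clusters, at 4.57 ± 0.12 and 4.75 ± 0.21 (exact p = 0.171).

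The first principal component held 69.6% of the variance and set the populations apart. Samples of the same population correlated at r = 0.984 to 0.997 across genes, and samples of different populations at 0.952 to 0.967 (genes are not independent replicates). The second component, with 13.3%, set samples 13 and 14 apart from the other 6. Xist, the noncoding RNA of X chromosome inactivation, was at 16.16 and 16.27 in samples 13 and 14 and between 5.89 and 9.32 in the other samples. The Y-linked gene Uty was at 5.49 and 5.56 in samples 13 and 14 and between 9.65 and 10.06 in the others. Cwc22 (added), a splicing factor, lay between 7.86 and 9.43 in samples 13 to 16 and between 13.47 and 14.7 in samples 17 to 20, in both populations. The median of the array's negative control rows was 6.81 ± 0.02 in the CD90-negative and 6.64 ± 0.045 in the CD90-positive samples (exact permutation test, p = 0.0286). This lay above the median of all transcript clusters. The array's background rows were lower, at 3.26 ± 0.012 and 3.27 ± 0.059. A mean below the negative control rows is therefore a caution about its size and does not show that a transcript was absent.

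**Figure D1:**
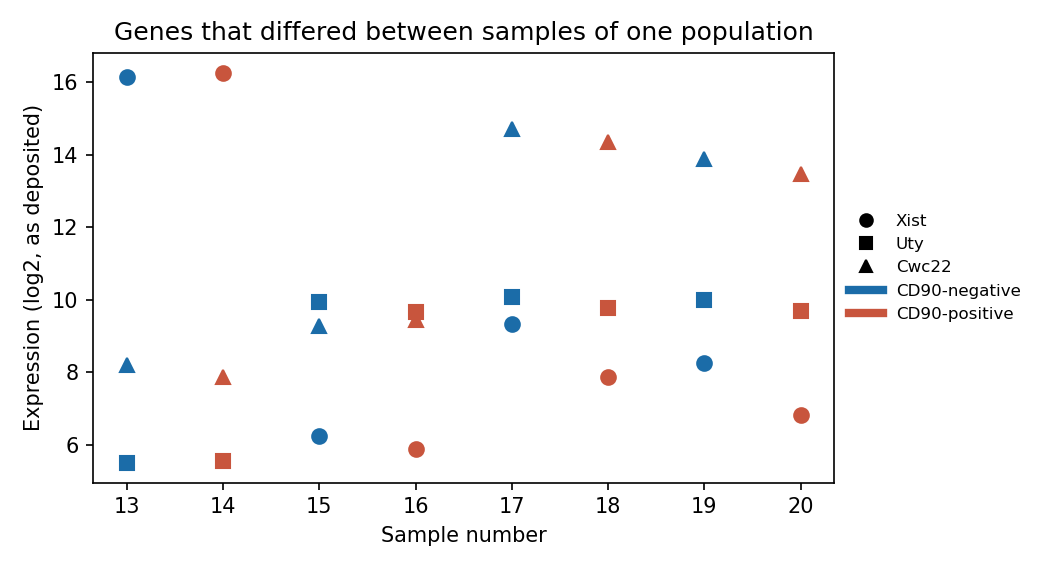
Expression of Xist, Uty and Cwc22 (log2, as deposited) in each of the 8 samples, by sample number; colour gives the sorted population and symbol the gene. Xist was at 16.16 and 16.27 in samples 13 and 14, and Cwc22 was at 13.47 or higher in samples 17 to 20.

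Of 17221 genes tested, 2417 were higher and 2701 lower in the CD90-positive population (limma adjusted p under 0.05), together 29.7% of the genes. Of these, 652 were higher and 587 lower by at least 2-fold. The values of the populations did not overlap in 32.3% of all genes tested, where chance gives 2.86%. The 12 highest differences belonged to Edil3, C4b, Lepr, Cntn1, Hapln1, Kcna1, Cdh19, Mgp, Grem1, Sfrp1, C4a and Eln, and ran from 6.55 for Edil3 to 4.77 for Eln. The CD90-negative means of Edil3, Cntn1, Hapln1, Kcna1 and Cdh19 lay below the median of the negative control rows, so their differences and their order are not exact; the same holds for any gene whose mean lay below it in 1 or both populations. Of the genes named in the text, Plxnc1, Plxnb3, Wnt2, Rspo1, Gdf6, Chrdl2, Ltbp2, Notch3, Mmp13, Ptgfr, Cx3cr1, Cd3e, Cd79a, Prox1, Lmod1, Ret, Uchl1, Upk3b, Gpm6a, Slc15a2, Pecam1 and Ptprc had both means below it. Edil3, an integrin-binding matrix protein, rose from 6.53 ± 0.75 to 13.09 ± 0.29 (limma adjusted p = 2.65e-06). The leptin receptor gene Lepr rose from 8.47 ± 0.31 to 14.18 ± 0.42. Mgp, a matrix inhibitor of calcification, rose from 9.82 ± 1.64 to 14.78 ± 0.71. Hapln1 codes for a link protein of hyaluronan and proteoglycans, and Cntn1 for a cell adhesion molecule of neurons. Cntn1 was at 7.78 in sample 14 and between 12.69 and 13 in the other CD90-positive samples. Kcna1, a potassium channel subunit, and Cdh19, a cadherin of glial cells, belong to the fixed list of enteric glia genes, all 10 tested members of which rose. C4a and C4b, genes of complement factor C4, are near-identical copies, so the values of each are uncertain.

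The 12 lowest differences belonged to Sox6, Ednrb, Cybrd1, Casq2, Bmp3, Tspan13, Glp2r, Bean1, Rerg, Slc6a11, Nrg1 and Wnt5a, and ran from -7.05 for Sox6 to -4.6 for Wnt5a. The transcription factor gene Sox6 was at 14.36 ± 0.22 in CD90-negative and 7.3 ± 0.58 in CD90-positive samples, and the endothelin receptor gene Ednrb at 14.19 ± 0.34 and 7.42 ± 0.51 (limma adjusted p = 5.41e-07 and 5.76e-07). Cybrd1, an iron-regulated cytochrome b reductase, fell from 14.98 ± 0.64 to 8.47 ± 0.81. Glp2r, the receptor for glucagon-like peptide 2, fell from 10.6 ± 0.37 to 5.52 ± 0.15, a value below the negative control rows. Slc6a11, a GABA transporter, fell from 11.8 ± 0.31 to 7.04 ± 0.55. Casq2, a calcium-binding protein of the sarcoplasmic reticulum, fell from 11.58 ± 0.86 to 6.37 ± 0.98, also below them.

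**Figure D2:**
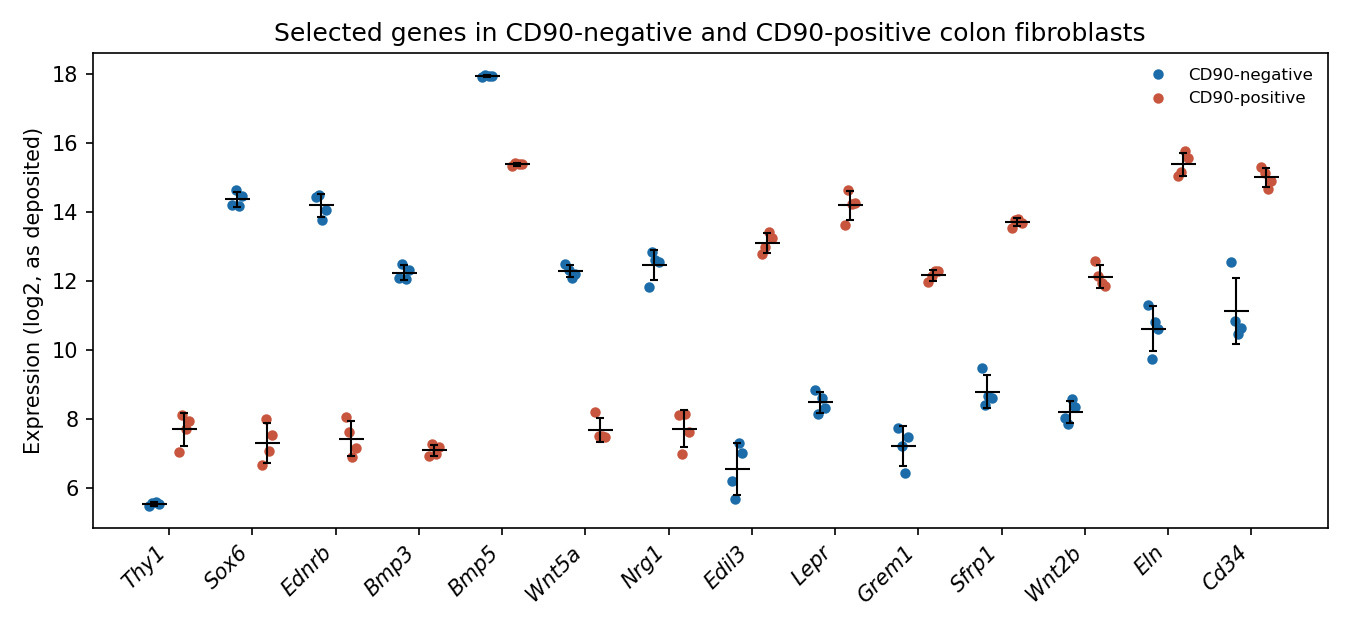
Expression (log2, as deposited) of 14 genes in the 4 CD90-negative and 4 CD90-positive samples; points are samples, horizontal lines the means and bars the SD. Sox6 fell from 14.36 to 7.3, and Edil3 rose from 6.53 to 13.09.

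Genes known from fibroblasts next to the epithelium were lower in the CD90-positive population, and genes known from fibroblasts deeper in the wall were higher. Of 17 tested members of the list of subepithelial PDGFRA-high fibroblast genes, 15 fell and 1 rose, with the same counts adjusted over the list alone. Pdgfra itself, after which the list is named, was not among the measured genes. The list's median difference was -3.41 (camera adjusted p = 3.6e-13, and adjusted p = 0.0118 with an estimated correlation). F3, the tissue factor gene, fell from 15.06 ± 0.072 to 11.13 ± 0.2. The member that rose was Postn (added), a matricellular protein, at 17.14 ± 0.12 and 17.67 ± 0.05. Of 18 tested members of the list of CD34-CD81 adventitial fibroblast genes, 16 rose and 0 fell, and 17 rose adjusted over the list alone. The median difference was 2.16 (camera adjusted p = 6.64e-10, but adjusted p = 0.289 with an estimated correlation). Cd34, a surface sialomucin, rose from 11.11 ± 0.96 to 14.99 ± 0.28. Mfap5, a microfibril glycoprotein, rose from 9.91 ± 1.07 to 14.17 ± 0.23, and Clec3b, the tetranectin gene, from 11.51 ± 0.25 to 14.4 ± 0.087.

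**Figure D3:**
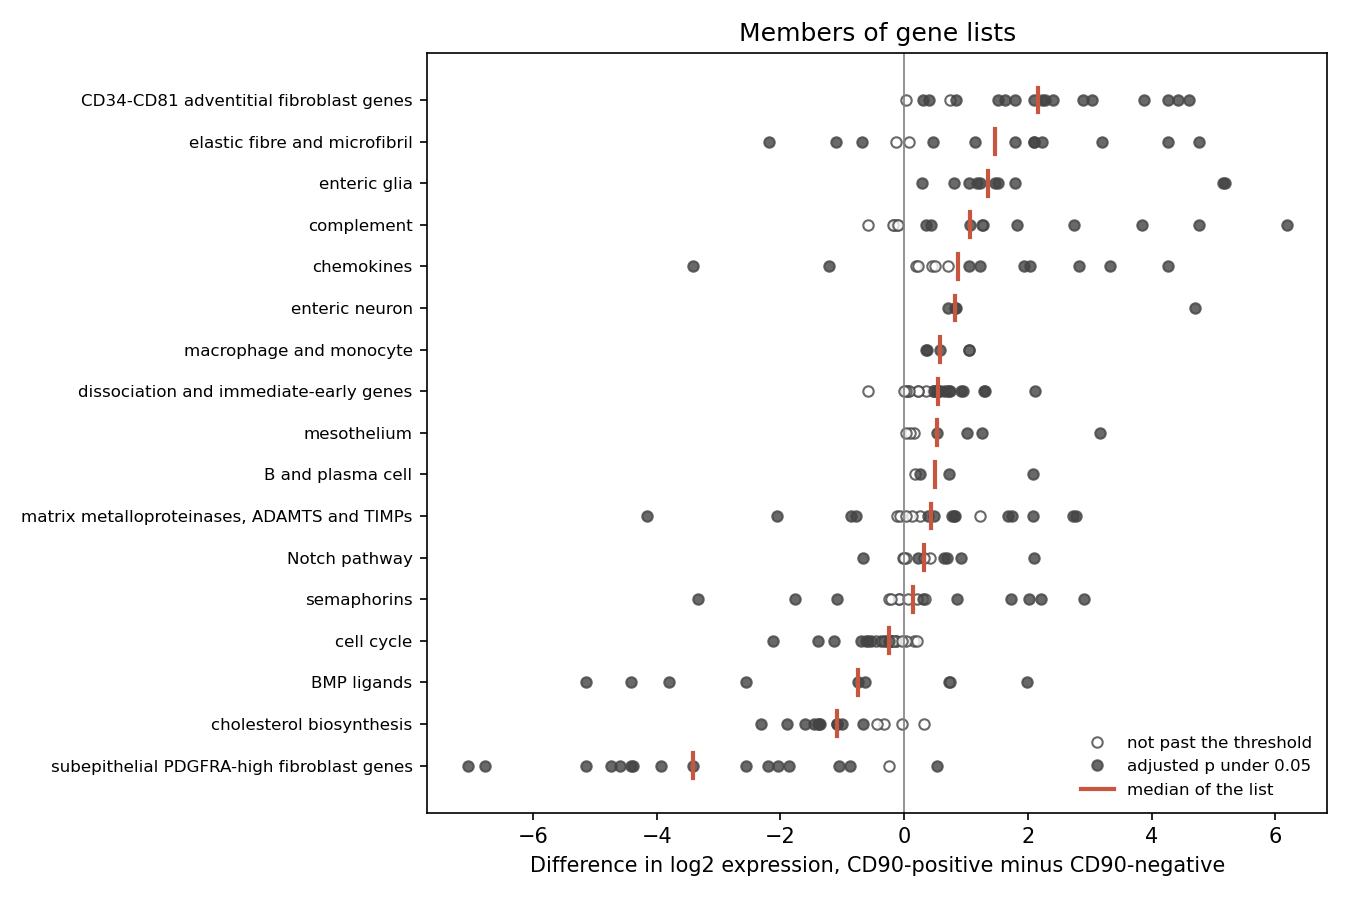
Difference in log2 expression, CD90-positive minus CD90-negative, of each tested member of the 16 gene lists called by camera and of the semaphorins; filled points passed an adjusted p of 0.05 and vertical lines are list medians. The medians ran from -3.41 for the subepithelial list to 2.16 for the adventitial list.

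Genes of Wnt and BMP signalling moved in both directions. Of 9 tested BMP ligands, 6 fell and 2 rose, with the same counts adjusted over the list alone (median difference -0.74; camera adjusted p = 0.00822, and adjusted p = 0.264 with an estimated correlation). Bmp5 fell from 17.93 ± 0.028 to 15.37 ± 0.045, Bmp7 from 14.11 ± 0.12 to 9.7 ± 0.24, Bmp3 from 12.23 ± 0.2 to 7.08 ± 0.16 and Bmp2 from 10.97 ± 0.18 to 7.17 ± 0.27. Bmp3, Bmp5 and Bmp7 also belong to the subepithelial list. The ligands that rose were Bmp6 (added), from 12.95 ± 0.17 to 14.93 ± 0.29, and Gdf6 (added), from 5.51 ± 0.11 to 6.23 ± 0.18, below the negative control rows in both populations. Of 10 BMP antagonists, 4 rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.94). Grem1, a secreted antagonist of BMP2 and BMP4, rose from 7.21 ± 0.58 to 12.16 ± 0.16 and Fstl1 by 0.9, and Fstl3 and Chrdl2 (both added) rose by 0.48 and 0.41. Twsg1 fell by 2.12, Nbl1 by 2.56, and Fst and Chrd (both added) by 1.35 and 0.57. Chrdl2 passed with an adjusted p of 0.0181, and without sample 17 its limma adjusted p was 0.0515.

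Of 7 tested Wnt ligands and R-spondins, 4 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.135). Wnt2b rose from 8.19 ± 0.33 to 12.11 ± 0.33, and Rspo3, which amplifies Wnt signals at intestinal stem cells, from 6.17 ± 0.33 to 9.23 ± 0.17. Wnt2 and Rspo1, with means below the negative control rows in both populations, were called higher, and Wnt5a, a ligand of noncanonical Wnt signalling, fell from 12.27 ± 0.18 to 7.66 ± 0.34. Wnt2 passed the filter only through its CD90-positive values, since its CD90-negative values were 4.85 or lower. Without sample 17 Rspo1 lost its call (limma adjusted p = 0.0535), and without a filter on dim clusters the list was called higher (camera adjusted p = 0.00199). Of 7 secreted Wnt inhibitors, 4 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.389). Sfrp1 rose from 8.78 ± 0.47 to 13.68 ± 0.12 and Sfrp2 by 0.85, and Frzb and Sfrp4 (both added) rose by 1.91 and 2.37. Wif1 fell from 10.37 ± 0.41 to 6.08 ± 0.31 and Dkk3 from 14.22 ± 0.16 to 13.02 ± 0.36. Sfrp4 had a limma adjusted p of 0.0347 and lost its call when any 1 of samples 14 to 20 was left out, with adjusted p up to 0.0926.

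Of 15 tested epithelial growth factors and mitogens, 5 rose and 4 fell, and 6 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.682; the median difference was 0.29 and the mean -0.33, and the test pointed higher). Hgf, the hepatocyte growth factor gene, rose from 12.47 ± 0.13 to 14.45 ± 0.25, and Fgf7, Fgf10, Igf1 and Fgf2 (all added) rose by 0.88, 0.77, 0.55 and 0.82. Nrg1, a ligand of ERBB receptors, fell from 12.44 ± 0.43 to 7.71 ± 0.54, Fgf9 from 10.74 ± 0.25 to 6.69 ± 0.47, Btc by 1.64 and Ereg (added) by 0.87. Fgf2 and Ereg lost their calls without single samples: Fgf2 without sample 15, 17 or 19, with limma adjusted p up to 0.0603, and Ereg without sample 17 or 19, up to 0.057.

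Semaphorins are secreted or membrane-bound guidance cues that bind plexins and neuropilins. Their list was fixed beforehand, but with background knowledge that linked semaphorins to CD90-positive colon fibroblasts, so it was not a blind choice. Of 16 tested semaphorins, 6 rose and 3 fell, and 6 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.393). Sema3c rose from 11.26 ± 0.37 to 13.27 ± 0.24, Sema3d from 7.06 ± 0.92 to 9.95 ± 0.69, Sema3a (added) from 6.21 ± 0.25 to 8.42 ± 0.68 and Sema3b from 6.42 ± 0.15 to 8.14 ± 0.14. Sema3f fell from 12.29 ± 0.095 to 8.95 ± 0.15, Sema6a by 1.77 and Sema4c (added) by 1.09. Of 10 plexins and neuropilins, 3 rose and 2 fell, and 4 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.701; the median difference was -0.074 and the mean 0.2, and the test pointed higher). Plxna2 rose from 7.43 ± 0.26 to 9.39 ± 0.16, Plxnc1 by 1.34 and Plxnb3 by 0.89, and Plxna1 and Nrp2 (added) fell by 1.03 and 0.96. Plxnc1 and Plxnb3 passed the filter only through their CD90-positive values, since their CD90-negative values were 5.2 or lower.

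Elastic fibre genes were higher in the CD90-positive population. Of 14 tested members of the elastic fibre and microfibril list, 9 rose and 3 fell, also when adjusted over the list alone (median difference 1.47; camera adjusted p = 0.00461, and adjusted p = 0.289 with an estimated correlation). Eln, the elastin gene, rose from 10.61 ± 0.66 to 15.37 ± 0.34, Mfap4 from 8.24 ± 0.59 to 11.45 ± 0.23 and Ltbp4 from 15.25 ± 0.066 to 16.4 ± 0.031. Ltbp2, Fbn2 and Emilin1 (all added) fell by 0.68, 2.18 and 1.11. Of 20 matrix metalloproteinases, ADAMTS proteases and TIMP inhibitors, 10 rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.0411, and adjusted p = 0.349 with an estimated correlation). Mmp11 rose from 7.46 ± 0.24 to 10.23 ± 0.11 and Adamts10 by 1.67, while Mmp10 fell from 10.36 ± 0.49 to 6.21 ± 0.27, Adamts9 by 2.05, and Mmp2 and Mmp13 (both added) by 0.86 and 0.78. Without sample 14 this list was not called (camera adjusted p = 0.0902).

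Other matrix lists moved in both directions and were not called. Of 22 fibrillar collagen and processing genes, 7 rose and 6 fell, and 7 rose and 7 fell adjusted over the list alone (camera adjusted p = 0.871; the median difference was -0.099 and the mean 0.049, and the test pointed lower). The lysyl oxidase-like genes Loxl1 and Loxl4, whose enzymes cross-link collagen and elastin, rose by 2.21 and fell by 1.73. Of 21 basement membrane genes, 5 rose and 7 fell, also when adjusted over the list alone (camera adjusted p = 0.466). Col15a1 rose from 9.62 ± 0.12 to 13.62 ± 0.082, while Col4a5 and Col4a6, chains of collagen IV, fell by 3.59 and 3.73 and the laminin gene Lamb1 by 1.55. Of 22 proteoglycan and matricellular genes, 10 rose and 7 fell, also when adjusted over the list alone (camera adjusted p = 0.389). Vcan, the versican gene, rose by 1.8, and Ogn and Podn fell by 1.62 and 1.81. Of 16 pan-fibroblast genes, 8 rose and 4 fell, and 8 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.389). Their mean was higher by 0.56 (exact permutation test, p = 0.0286, adjusted p = 0.0413 over 13 cell type lists), with an exact p of 0.0571 without sample 14. The list means of the populations did not overlap in either case. Dcn, the decorin gene, rose from 17.95 ± 0.26 to 18.7 ± 0.074, Col6a1, Col6a2 and Col6a3 fell by 1.14, 1.08 and 1.46, and Fn1 was at 17.82 ± 0.068 and 17.85 ± 0.11 (limma adjusted p = 0.801).

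Chemokine and complement genes were higher in the CD90-positive population. Of 14 tested chemokines, 7 rose and 2 fell, and 9 rose and 2 fell adjusted over the list alone (median difference 0.87; camera adjusted p = 0.0023, and adjusted p = 0.367 with an estimated correlation). Ccl11, the eotaxin gene, rose from 7.72 ± 0.54 to 11.98 ± 0.37, Ccl8 from 6.82 ± 0.35 to 10.15 ± 0.46 and Cxcl16 by 1.04. The chemokines that fell were Cxcl14, from 11.85 ± 0.46 to 8.44 ± 0.74, and Cxcl12 (added), by 1.21. Of 15 complement genes, 9 rose and 0 fell, also when adjusted over the list alone (median difference 1.06; camera adjusted p = 0.00133, and adjusted p = 0.289 with an estimated correlation). Among them was Cd59a, an inhibitor of the membrane attack complex, which rose by 1.83. Of 16 cytokines, 6 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.0794). Tnfsf13b, which codes for the B cell survival factor BAFF, rose from 10.35 ± 0.26 to 14.23 ± 0.22, Il6 from 8.03 ± 0.74 to 11.07 ± 0.15 and Il7 by 1.23. Il34 and Csf1 (both added), ligands of the receptor of macrophage colony-stimulating factor, fell by 2.33 and 0.4. Without sample 13 the cytokine list was called higher (camera adjusted p = 0.0364), and after another quantile normalization Csf1 lost its call (limma adjusted p = 0.125).

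Contractile genes went both ways. Of 18 tested smooth muscle and myofibroblast genes, 10 fell and 6 rose, also when adjusted over the list alone (camera adjusted p = 0.12). Acta2, smooth muscle alpha-actin, fell from 15.99 ± 0.11 to 13.86 ± 0.86, Myl9 by 2.4, Actn1 by 2.35 and Cald1 by 1.58. The members that rose were Hhip, from 9.87 ± 1.01 to 13.19 ± 1.08, and Cnn1, Actg2, Synm, Des and Lmod1 (all added), by 1.77, 1.3, 1.12, 0.96 and 0.92. Hhip codes for a hedgehog-binding protein, and the others for calponin, smooth muscle gamma-actin, intermediate filament proteins and a leiomodin. The mean of the list was 10.51 in sample 14 and between 9.42 and 9.45 in the other CD90-positive samples, and without sample 14 or without a filter on dim clusters the list was called lower (camera adjusted p = 0.00653 and 0.021). Actg2 had a limma adjusted p of 0.0353 and lost its call without sample 15, 17, 18 or 19, with adjusted p up to 0.0863, and without a filter on dim clusters (0.0506).

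Of 10 pericyte genes, 4 fell and 3 rose, and 5 fell and 3 rose adjusted over the list alone (camera adjusted p = 0.373). Their mean went from 8.81 ± 0.11 to 8.18 ± 0.098 (exact permutation test, p = 0.0286, adjusted p = 0.0413). Abcc9 fell from 11.1 ± 0.055 to 7.73 ± 0.8, Gucy1b1 by 2.15, Cspg4 by 1.53 and Kcnj8 (added) by 2.1, and Mcam, Rgs5 and Notch3 (all added) rose by 1.37, 1.49 and 0.23. Rgs5 and Notch3 lost their calls without single samples, Rgs5 without any 1 of samples 15 to 20, with limma adjusted p up to 0.0838, and Notch3 without sample 18 or 19, up to 0.0616. Rgs5 also lost its call with consecutive title numbers as a block (limma adjusted p = 0.0521), and Notch3 after another quantile normalization (0.0563). Of 5 genes of interstitial cells of Cajal, the pacemaker cells of the gut wall, 3 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 0.101). Their mean went from 10.43 ± 0.62 to 9.67 ± 0.18 (exact permutation test, p = 0.0286, adjusted p = 0.0413). The mean had an exact p of 0.0571 without sample 13 and 0.0857 without sample 16, 18 or 20, though its values did not overlap between populations. Without a filter on dim clusters the list was called lower (camera adjusted p = 0.0279). Cd44, a hyaluronan receptor, fell from 13.03 ± 0.27 to 10.86 ± 0.33, Elovl6 by 1.24 and Ano1 (added), a chloride channel, by 3.23, and the adhesion receptor gene Adgrd1 rose from 10.22 ± 0.88 to 13.99 ± 0.2. Kit, the remaining tested member, did not pass, at 7.91 ± 1.8 and 6.96 ± 0.47 (limma adjusted p = 0.405).

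Of 11 tested Notch pathway genes, 5 rose and 1 fell, also when adjusted over the list alone (median difference 0.32; camera adjusted p = 0.0238, and adjusted p = 0.289 with an estimated correlation). The target gene Hey1 rose from 7.1 ± 0.44 to 9.19 ± 0.15, Hes1 by 0.69 and the receptor gene Notch1 by 0.92, while the ligand gene Dll1 (added) fell by 0.66. Dll1 had a limma adjusted p of 0.0316 and lost its call without sample 14 or without any 1 of samples 16 to 20, with adjusted p up to 0.0738. Of 15 TGF-beta family ligands and regulators, 6 rose and 5 fell, also when adjusted over the list alone (camera adjusted p = 0.193). Tgfb3 rose from 10.12 ± 0.4 to 12.98 ± 0.19, and Tgfbi, a matrix protein induced by TGF-beta, fell from 15.02 ± 0.23 to 10.95 ± 0.58. Of 9 hedgehog pathway genes, Boc and Hhip rose by 0.85 and 3.33 and the receptor gene Ptch1 fell by 1.7 (2 rose and 1 fell, also when adjusted over the list alone; camera adjusted p = 0.599).

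Immediate-early genes, which respond to tissue dissociation and other stimuli, were higher in the CD90-positive population. Of 25 tested, 14 rose and 0 fell, also when adjusted over the list alone (median difference 0.54; camera adjusted p = 9.31e-06, and adjusted p = 0.349 with an estimated correlation). Atf3 rose from 13.09 ± 0.14 to 14.38 ± 0.13, Gadd45b by 0.95 and Egr1 by 0.53. Of 23 cell cycle genes, 9 fell and 0 rose, and 12 fell and 1 rose adjusted over the list alone (median difference -0.25; camera adjusted p = 0.00351, and adjusted p = 0.498 with an estimated correlation). Mki67 fell from 8.72 ± 0.65 to 6.6 ± 0.57, Bub1b from 6.96 ± 0.067 to 5.56 ± 0.12 and Top2a by 1.14. Of 15 cholesterol biosynthesis genes, 11 fell and 0 rose, and 13 fell adjusted over the list alone (median difference -1.09; camera adjusted p = 3.08e-05, and adjusted p = 0.411 with an estimated correlation). Sqle, the squalene epoxidase gene, fell from 11.58 ± 0.48 to 9.26 ± 0.26, and Fdps from 10.59 ± 0.39 to 8.68 ± 0.36. Of 18 glycolysis and hypoxia genes, 7 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 0.0833). Pfkp and Pkm fell by 0.85 and 1.07, and Ndrg1 rose by 0.95. This list was called lower without a filter on dim clusters and without sample 15 (camera adjusted p = 0.0111 and 0.0117).

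Markers of enteric glia, the glial cells of the gut's nervous system, were higher in the CD90-positive samples. All 10 tested members rose, also when adjusted over the list alone (median difference 1.35; camera adjusted p = 7.66e-07, and adjusted p = 0.289 with an estimated correlation). Kcna1 rose from 5.57 ± 0.32 to 10.76 ± 1.04 and Cdh19 from 5.28 ± 0.32 to 10.44 ± 1.19. The glial transcription factor gene Sox10 (added) was at 5.64 ± 0.064 and 6.87 ± 0.29, and S100b (added) at 5.71 ± 0.2 and 6.88 ± 0.32. The sodium channel gene Scn7a was bright in both populations, at 14.55 ± 0.17 and 16.07 ± 0.43. The mean of the list was 6.52 ± 0.11 and 8.49 ± 0.5 (exact permutation test, p = 0.0286, adjusted p = 0.0413 over 13 cell type lists). Of 14 measured enteric neuron genes only 4 passed the filter on dim clusters. All 4 rose, also when adjusted over the list alone (camera adjusted p = 0.000822, and adjusted p = 0.166 with an estimated correlation). The median difference was 0.82 and the mean 1.76, which rested mostly on Stmn2, higher by 4.7. Stmn2 rose from 6.39 ± 0.26 to 11.08 ± 0.51, and Gap43 by 0.83. Ret and Uchl1 were called higher with means below the negative control rows in both populations. Like Wnt2, Plxnc1 and Plxnb3, Ret passed the filter only through its CD90-positive values, since its CD90-negative values were 5.24 or lower. Some counted members that are not named share this limit. Of 7 mesothelial genes, 4 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.0101, and adjusted p = 0.289 with an estimated correlation). Igfbp5 rose from 12.36 ± 0.68 to 15.52 ± 0.49, Upk3b by 1.26, Gpm6a by 1.02 and Rspo1 by 0.53. Without sample 14 the mesothelial list was not called (camera adjusted p = 0.0509), and without sample 17 Rspo1 was not (limma adjusted p = 0.0535).

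Of 5 macrophage and monocyte genes, 4 rose and 0 fell, and 5 rose adjusted over the list alone (camera adjusted p = 0.0154, and adjusted p = 0.289 with an estimated correlation). Cd68 rose from 8.75 ± 0.12 to 9.8 ± 0.49 and Cx3cr1 from 5.88 ± 0.2 to 6.46 ± 0.18. Of 4 B and plasma cell genes, 3 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.0448, and adjusted p = 0.316 with an estimated correlation). These were Xbp1, Jchain and Cd79a, with differences of 0.72, 2.08 and 0.26. The list lost its call without sample 17, 19 or 20 (camera adjusted p = 0.0776, 0.0642 and 0.0602), and Cd79a without any 1 of samples 15 to 20 (limma adjusted p up to 0.0862). Cd79a also lost its call with consecutive title numbers as a block and after another quantile normalization (limma adjusted p = 0.0514 and 0.082). None of the 4 tested pan-leukocyte genes passed, although the mean of this list, near the dim end of the scale, was 5.33 ± 0.053 and 5.51 ± 0.042 (exact permutation test, p = 0.0286, adjusted p = 0.0413). Without a filter on dim clusters this list was called higher (camera adjusted p = 0.0212), while its mean had an exact p of 0.0571. The means of the enteric neuron, mesothelial, B and plasma cell and macrophage lists were higher by 1.76, 0.9, 0.81 and 0.68 (exact permutation tests, p = 0.0286 and adjusted p = 0.0413 each). The macrophage mean had an exact p of 0.0571 without sample 13, 15, 17 or 19, and the B and plasma cell mean without sample 14, 16, 18 or 20. In all these settings every CD90-positive mean of these lists still lay above every CD90-negative one. Without sample 16, 18 or 20 the mean of no cell type list passed the adjusted threshold. There the glial, enteric neuron, mesothelial, pericyte, macrophage, pan-leukocyte and pan-fibroblast means each kept an exact p of 0.0286. That is the smallest that 3 samples against 4 can give, so they missed the threshold only through the adjustment. Of 3 T cell genes 1 rose, and 2 adjusted over the list alone. It was Cd3e, higher by 0.74, with a limma adjusted p of 0.0279 that ran up to 0.0762 when single samples were left out. Of the mast cell list 1 gene was tested and did not pass, and no erythroid gene passed the filter.

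Of 20 tested epithelial genes, 0 rose and 0 fell past the threshold, also when adjusted over the list alone (camera adjusted p = 0.476). Krt8 was at 10.73 ± 1.27 and 11.05 ± 1.18 and Car1 at 12.32 ± 1.64 and 13.15 ± 0.81, and Car1 was called higher with array weights (limma adjusted p = 0.0383). The mean of the epithelial list differed between samples of one population, with 8.74 in sample 13 and 8.68 in sample 20 against 7.18 to 7.84 in the other 6 samples, and without sample 13, or without samples 13 and 14, the list was called higher (camera adjusted p = 0.0196 and 0.00579). Of 9 blood endothelial genes, 2 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.16). Tek rose by 1.84 and Ramp2 by 0.51, and Ramp2 lost its call without sample 16, 17 or 19 (limma adjusted p up to 0.0576). The endothelial list was called higher without sample 14, without samples 13 and 14, and without a filter on dim clusters (camera adjusted p = 0.0452, 0.00783 and 0.0494). Of 5 lymphatic endothelial genes, Sema3d rose by 2.9 and Lyve1 and Prox1 fell by 1.09 and 0.49 (1 rose and 2 fell, also when adjusted over the list alone; camera adjusted p = 0.393, with a median difference of -0.32, a mean of 0.19 and a test that pointed lower). The mean of this list had an exact p of 0.314, and without sample 13 it was higher by 0.32 (exact p = 0.0286).

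**Figure D4:**
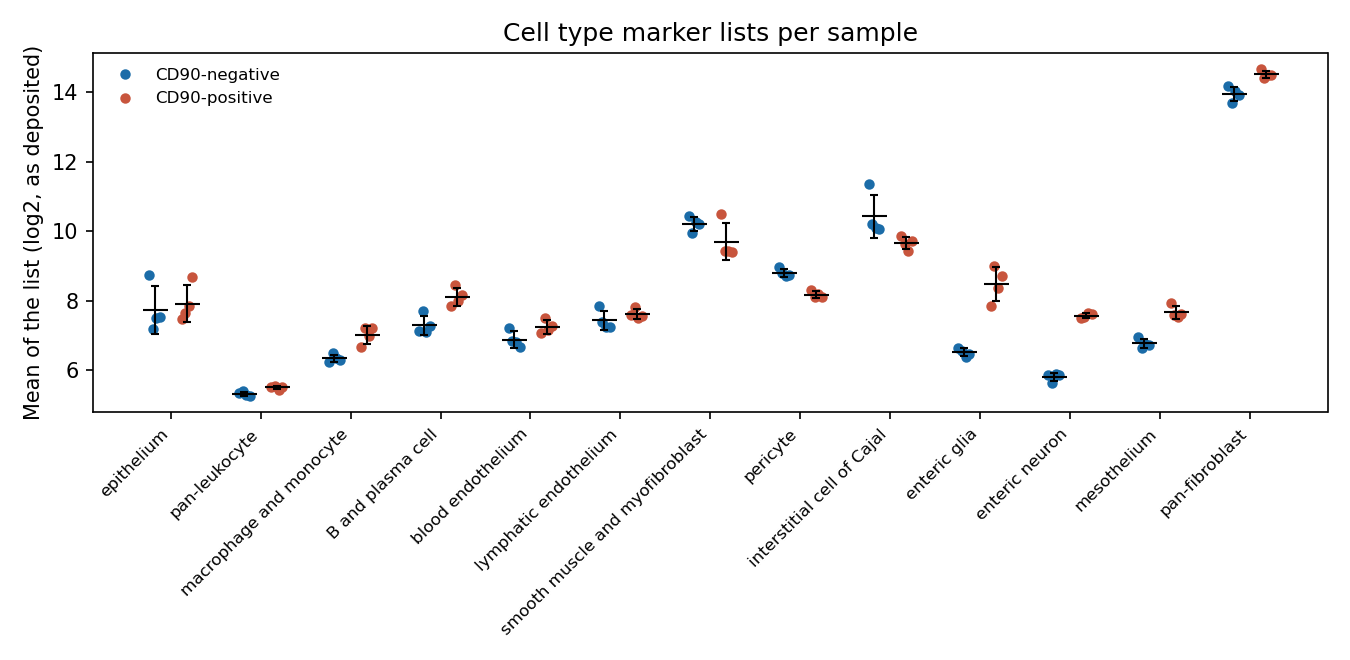
Mean log2 expression (as deposited) of the tested members of 13 cell type marker lists in each sample; points are samples, horizontal lines the means and bars the SD of 4 samples. The enteric glia list lay at 6.52 in CD90-negative and 8.49 in CD90-positive samples, and the epithelial list at 7.74 and 7.91.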

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

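The tests in this part on carry-over of other cells were chosen after the result was seen; the second glial list and the splits of the samples were set before theirs were.

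More genes were called between the populations than under any other split of the samples, but the splits alone cannot exclude chance. They took the 8 samples as exchangeable, although both populations came from the same 4 mice. Swaps within 4 pairs could give no p under 0.125. The other splits also mix the populations, so the difference between these adds to the spread within their groups. Of the 35 ways to split the 8 samples into 4 and 4, 1 gave as many genes, the real one, with 5118, and the highest other gave 10. For gene lists also 1 of 35 splits gave as many, the real one with 16 lists, but another split gave 14, so camera with a preset correlation also calls lists where almost no gene is called. Among clusters that name no single gene, outside the main comparison, 15890 passed the filter, and 1617 were higher and 2037 lower in the CD90-positive population, together 3654. Here too 1 of 35 splits gave as many, and the highest other gave 292.

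Glial markers rose in the CD90-positive population, all 10 of 10 tested. Enteric glial cells in the CD90-positive gate remain a candidate explanation: of a second list of 19 glial genes, written before their values were seen, 15 were tested and 73.3% of these were called higher, against 14% of all genes, with 1 lower. In that second list Ptprz1 (added) passed the filter only through its CD90-positive values, with a CD90-negative mean of 4.89 ± 0.12. The gate excluded cells by markers of epithelium, leukocytes and endothelium but by none of glia, although any such cell would also have had to carry gp38. A carry-over of all cells other than fibroblasts alike cannot be told apart from this. The glial list rose by 1.79 more than the epithelial list (exact permutation test, p = 0.0286). Epithelial markers, however, were bright in both populations and could hide a small rise. The enteric neuron, mesothelial, B and plasma cell and macrophage lists rose too, by 1.76, 0.9, 0.81 and 0.68, the enteric neuron mean mostly through Stmn2. The pericyte, smooth muscle and Cajal cell lists, bright in both populations, were lower by 0.63, 0.51 and 0.76 (exact permutation tests, p = 0.0286, 0.143 and 0.0286). Their members went both ways, so these means cannot decide about a carry-over. Of 18 smooth muscle genes 10 fell and 6 rose. Of 10 pericyte genes 4 fell and 3 rose, and of 5 Cajal cell genes 3 fell and 1 rose. Smooth muscle was lower by 0.78 without sample 14 (exact p = 0.0286), and Cajal cells by 0.46 without sample 13 (exact p = 0.0571). That CD90-positive fibroblasts themselves carry these transcripts stays open and was not tested.

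Single samples stood far from the other 3 of their population in 46 of the 418 groups of 4 values looked at, where chance gives about 1 in 20, or 21. That rate takes the groups as independent, which genes measured in the same samples are not. Sample 14 accounted for 27 of the flagged groups, sample 13 for 12 and sample 15 for 5. Samples 13 and 14 were also the only ones high in Xist and low in Uty, and the second principal component set them apart. Their flags may therefore reflect a difference shared by both samples rather than faults of single arrays, which was not tested. In sample 14 the lowest CD90-positive values were Cntn1 7.78, Hapln1 11.19, Vcan 13.78, Ccl8 9.47, Mki67 5.76, Uty 5.56, Igfbp5 14.79, Cd3e 5.7, Fn1 17.68, Vegfc 10.72, B2m 15.66, Ereg 10.61 and Il34 7.39, and the median of the negative control rows, 6.58. The highest were Pdpn 13.54, Mgp 15.85, Casq2 7.84, Wnt5a 8.18, Dkk3 13.55, Myl9 12.14, Hhip 14.81, Upk3b 6.92, Mmp2 15.37, Cnn1 9.65, Actg2 11.79 and Synm 10.34, and the mean of the smooth muscle list, 10.51. In sample 13 the lowest CD90-negative values were Cald1 12.87, Mki67 7.74, Uty 5.49 and Prox1 6.06. The highest were Glp2r 11.15, Sema3d 8.44, Tek 9.75, Rdh10 15.55, Ptgis 10.16, Fstl3 7.7 and Cnn1 7.48, and the mean of the list of interstitial cells of Cajal, 11.35. In sample 15 Ptprc was highest at 4.74, and Cntn1 at 5.62, Wif1 at 9.76, Ret at 5.09 and the mean of the enteric neuron list at 5.64 were lowest. Mmp13 was highest in sample 16 at 5, where the other 3 lay between 4.86 and 4.87, and Dll1 in sample 20 at 7.67, where the other 3 were at 7.64.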

How the results depend on the processing

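The settings without samples 13 and 14 and with samples 17 to 20 as a block were chosen after seeing the data, the others before the data were examined. Gene counts stayed within 1.5 times of 2417 higher and 2701 lower under every setting but a minimum difference of 1 (log2), which by its construction left 652 and 587. Other settings gave 1634 to 3133 higher and 1939 to 3891 lower, the most with array weights; without 1 sample each the ranges were 1852 to 2316 and 1939 to 2818. The block fits over all 24 ways to pair the populations gave 1776 to 2772 higher and 1828 to 3170 lower, the most for consecutive title numbers. Of the 42 lists tested, camera called 12 higher and 4 lower. With an estimated correlation it called 0 higher and 1 lower, and without a filter on dim clusters 15 and 7. The fry rotation test, which does not compare a list with other genes, called 19 higher and 13 lower. The estimated correlation was 0.73 for cholesterol biosynthesis and 0.542 for the adventitial list, far above the preset of 0.01. BMP ligands lost their call with an estimate of -0.0562, so a high correlation does not account for every lost call. The cause of the differences between these tests was not tested further. Without 1 sample each, 10 to 14 lists were called higher and 4 to 5 lower. Thy1 stayed higher by 2.03 to 2.39 without 1 sample each; without samples 13 and 14 it was higher by 2.37, where the smallest p that 3 samples against 3 allow is 0.1 by construction. Likewise 9 cell type list means passed the exact test, 0 without samples 13 and 14, and 0 to 8 without 1 sample each, since 0 passed without sample 16, 18 or 20. In those settings means such as that of enteric glia kept the smallest exact p possible, 0.0286, and missed the threshold only through the adjustment. The fry test turned the direction of 4 lists that camera did not call: angiogenic factors and BMP antagonists were lower (adjusted p = 0.000362 and 0.0204), and semaphorins and epithelial growth factors did not pass (0.683 and 0.1). No list mean, list or named gene that was called reversed under any setting, but some that were not called turned sign, among them the epithelial mean and Epcam without sample 20. Of 191 named genes tested, 16 changed side of the threshold under some setting. Array brightness over background limits genes near the dim end, among them Ptprc and Cd79a.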

Other observations

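Angiogenic factors moved in both directions. Of 17 tested, 3 rose and 4 fell, and 4 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.545). Edn3, the endothelin 3 gene, fell from 9.36 ± 0.065 to 6.45 ± 0.13 and Vegfa from 13.25 ± 0.094 to 10.91 ± 0.043, while Vegfc rose from 9.29 ± 0.21 to 11.19 ± 0.32 and Pgf from 6.38 ± 0.31 to 9.6 ± 0.61 (n = 4 in each population, limma). Of 10 retinoid genes, 2 rose and 4 fell, and 3 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.603). Aldh1a1, a retinaldehyde dehydrogenase, fell from 13.54 ± 0.1 to 9.85 ± 0.37 and Rdh10 by 1.29, while Aldh1a3 rose from 6.52 ± 0.34 to 9.45 ± 0.51 and the receptor gene Rarb by 0.9.

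Of 14 prostaglandin genes, 2 rose and 4 fell, and 3 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.927; the median difference was 0.0081 and the mean -0.066, and the test pointed lower). The receptor genes Ptgir and Ptgfr rose by 1.38 and 0.71, and Pla2g4a and Ptgis, which act in synthesis, fell by 1.09 and 1.32. Of 20 interferon-stimulated genes, 4 rose and 5 fell, and 4 rose and 8 fell adjusted over the list alone (camera adjusted p = 0.306), with Usp18 lower by 1.4. Of 11 antigen presentation genes, 1 rose and 3 fell, and 2 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.94; the median difference was 0.0031 and the mean 0.034, and the test pointed lower). B2m rose from 15.22 ± 0.16 to 15.78 ± 0.084.

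The tests of Cwc22 and of the pairs of title numbers were chosen after the result was seen; the splits were set before. Cwc22 and 7 pseudogenes with neighbouring symbols, among them Gm13691, were higher in samples 17 to 20 than in samples 13 to 16, Cwc22 by 5.56 in the CD90-negative and by 5.26 in the CD90-positive samples. Samples 13 to 16 and 17 to 20 were taken as a possible batch by title number after samples 17 and 19, and 18 and 20, were seen to correlate most closely, at r = 0.997 and 0.996 across genes. The limma fit with the population as a term called 10 genes, these 8 and 2 others, among them Slc15a2. In a fit without that term, this division also called 292 of 15890 tested clusters that name no single gene. Of the 8 genes 5 had identical values in every sample, so they are not separate measurements. Of 18 splits that keep 2 samples of each population on each side, 1 gave as many genes and the highest other gave 0, but 18 splits are too few for a share under 0.05. Of the 17213 other genes 0 moved by 4 or more, but the 8 were picked for their shift, others moved by up to 3.26, and 8.14% had an unadjusted p under 0.05. A batch of array processing and a copy number or strain difference between mice therefore cannot be told apart. The labels give no batch and do not tie arrays to mice, and the shift was at least 5.26 in both populations. All mice are given as C57BL/6J, so a strain difference would go against that description.

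Neighbouring title numbers may mark the 2 populations of one mouse. Deviations from the population means correlated at 0.38 on average over the pairs 13 with 14, 15 with 16, 17 with 18 and 19 with 20 (across genes, which are not independent replicates). The highest mean of the other pairings was 0.33, so the exact p over the 24 pairings was 0.0417, the smallest they can give. Samples 13 and 14 alone were high in Xist and low in Uty. If each mouse gave both populations, only pairings of 13 with 14 were possible. Among these the mean correlation ran from 0.097 to 0.38, and they are too few for an exact p under 0.05. The value of 0.0417 therefore says little about the pairs other than 13 with 14. Pairing by neighbouring numbers is a hint from the data, not from the design. A fit with these pairs as a block called 2772 genes higher and 3170 lower against 2417 and 2701.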
